A study of Gallus gallus with 20 samples.

How the data were processed

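Chromatin immunoprecipitation with sequencing was done in primary chick limb mesenchymal cells that expressed OSR1, OSR2, EGR1, KLF2 or KLF4 with a triple FLAG tag from an RCAS retroviral vector, a virus that spreads through avian cells in culture. Per the labels' protocols, 24 cultures were pooled, chromatin was sheared to 200 to 500 bp, and 30 µg of chromatin was precipitated with 10 µg of anti-FLAG antibody. Libraries were sequenced as single reads of 50 bp. The 10 input samples and libraries of cells without a tagged factor were not analysed here.

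Per the submitters' processing notes, BWA, SAMtools and MACS2 were used with the galGal4 genome. Their versions and parameters, and whether each input served as the control of its library, are not given in the sources used here. The deposited file of each immunoprecipitated library is a peak list of its own, so the authors called peaks per library and did not pool replicates in these lists. Each deposited list gives per peak a fold enrichment (a linear ratio), a −log10 p-value, a −log10 q-value, a score and the offset of the summit. The deposited score was within 1 of the whole part of 10 times the −log10 p for all peaks and was not used further. The smallest deposited −log10 p was at most 1.61 in each list, so the lists were made at a relaxed threshold and hold many weak peaks. No read counts were given, so the depth per library is unknown and no counting interval on enrichment can be made. A library of lower depth or enrichment yields lower significance at the same binding, which is why sets of equal size were compared. No 2 lists shared more than 0.0159% of identical intervals, so all were counted as separate libraries.

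The samples were grouped by the factor and replicate number in their titles. Peaks were ranked within each list by −log10 p. Before the data were examined, the tests, the alternatives and the rule for named peaks were fixed. Library concordance was the mean Jaccard index of the 5000 strongest peaks, with an overlap of at least 1 bp, over the 5 replicate pairs, tested exactly against all divisions of the 10 libraries into pairs. Family overlap was tested exactly over the 15 choices of 2 separate factor pairs. Reproducible peaks had a −log10 q of at least 2 in both replicates and overlapped by at least 1 bp. Their overlap between factors was compared with 1000 circular shifts along assembled chromosomes, with Benjamini-Hochberg adjustment over the 10 pairs. The planned share of peaks at promoters was replaced, as foreseen, by the share on chromosomes 1 to 5, with an exact permutation F test. Named peaks were the 5 reproducible peaks on assembled chromosomes with the highest mean rank per factor, for OSR1 with OSR2, for KLF2 with KLF4, and for all factors together.

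Site classes were defined after the data were seen. Sites are merged regions of the 5000 strongest peaks of the 10 libraries. A common site is in all 10 sets. A factor-only site is in both replicates of a factor and outside the 20000 strongest peaks of every other library, and pair-only sites of 2 factors are defined likewise. In each class the 5 sites with the highest summed rank were taken, and those named in the text were picked among them after their values were seen. Exact Clopper-Pearson intervals at 95% cover counting error of sites alone. Chromosomes 1 to 5 were taken as macrochromosomes, 6 to 10 as intermediate, and those from 11 up with the linkage groups as microchromosomes. Summit distances were compared with 100000 sign-flip permutations.

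Alternatives were sets of 1000 and 20000 strongest peaks or all peaks with a −log10 q of at least 2, overlap of at least 0.5 of both peaks, overlap by base pairs, ranking by fold enrichment, a −log10 q of at least 5, an irreproducible discovery rate under 0.05, shifts of 20 to 200 kb, sets without sites shared by all, a replicate block, and leaving libraries out. The analyses of DNA motifs, GC content, promoters, gene lists and the factors' own genes were not run, because no sequence or annotation of galGal4 was used here, and the planned gene lists were not used.

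The code was tested on simulated data. With unstructured indices the division test gave p under 0.05 in 6.25% of 400 simulations, and in 99% when replicates were nearer by 2 SD. The F test on shares gave 5.75% of 400 simulations without a difference. Unrelated peak sets overlapped 1.02 times chance on average over 40 simulations, and 494 of 500 planted shared peaks were recovered above chance. For the irreproducible discovery rate, 96.0% of the reproducible pairs were called among 20000, with 4.59% false calls. All 700 planted common sites were found. Of 1000 planted EGR1-only sites 87.6% were found, since unrelated peaks of other libraries cover some sites by chance, and 9 sites were called for OSR1 with none planted. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.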

Results

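Genomic binding of 5 zinc-finger transcription factors was profiled in chick limb cells by chromatin immunoprecipitation with sequencing. The factors were OSR1 and OSR2, a pair of odd-skipped related proteins, EGR1, an early growth response protein that acts in tendon, and KLF2 and KLF4, a pair of Krüppel-like factors. Mesenchymal cells from limb buds at embryonic day 4.5 were infected with a replicating avian retrovirus that carried 1 FLAG-tagged factor, and were kept for 5 days as dense droplet cultures. Each factor had 2 immunoprecipitated libraries and 2 input samples, which makes 20 samples in 5 groups of immunoprecipitates and 5 of inputs. Peak lists of the 10 immunoprecipitated libraries were compared. The lists give no read counts, so the depth of each library is unknown. Fold enrichment and significance of a peak are the submitters' own values and are used to rank and describe peaks within a list. Nothing in the labels says whether the replicates of a factor came from separate cultures. The p-values of tests that regroup libraries therefore measure the spread between these libraries, which may be technical. Those from shifted peaks, summits or counts of sites rest on positions in the lists and measure no spread between libraries.

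The lists were long in every library, from 152519 peaks in KLF4 replicate 1 to 274427 in OSR1 replicate 1. All lists reached down to weak peaks, with a smallest −log10 p of at most 1.61. Peaks with a q-value of 0.01 or less numbered between 71801 in KLF4 replicate 1 and 202650 in EGR1 replicate 2. Enrichment at the 5000 strongest peaks was highest for EGR1, with a median of 12.4-fold in replicate 1 and 15.4-fold in replicate 2. It was 8.80-fold and 10.4-fold for OSR1, 9.97-fold and 9.74-fold for OSR2, and 7.55-fold and 9.87-fold for KLF4. The KLF2 replicates differed most, with 6.40-fold in replicate 1 and 12.8-fold in replicate 2. KLF2 replicate 1 also had the narrowest peaks, down to 54 bp where other lists started at 102 to 131 bp, and 20.6% of its 5000 strongest peaks lay on sequence not placed on a chromosome, against 5.88% to 9.24% in the other libraries.

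The first comparison asked whether replicates of a factor bound the same places more than different factors did. They did so on average, but not for each library. The Jaccard index of the 5000 strongest peaks, the number of shared peaks divided by the number found in either list, averaged 42.1% between replicates and 26.1% between libraries of different factors. EGR1 replicates shared most, at 61.5%, followed by OSR1 at 42.9%, OSR2 at 39.2%, KLF4 at 37.4% and KLF2 at 29.6%. The mean over replicate pairs was larger than chance pairing of the libraries gives (exact test over all divisions of the 10 libraries into 5 pairs, one-sided p = 0.00635). In 6 of the 10 libraries the nearest list was that of the same factor's other replicate. OSR1 replicate 1 lay nearest to OSR2 replicate 2 at 43.1%, OSR2 replicate 2 nearest to OSR1 replicate 2 at 47.6%, and OSR1 replicate 2 and KLF2 replicate 2 nearest to each other at 48.7%. For KLF2 replicate 2, the other KLF2 library came in place 6.

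**Figure D1:**
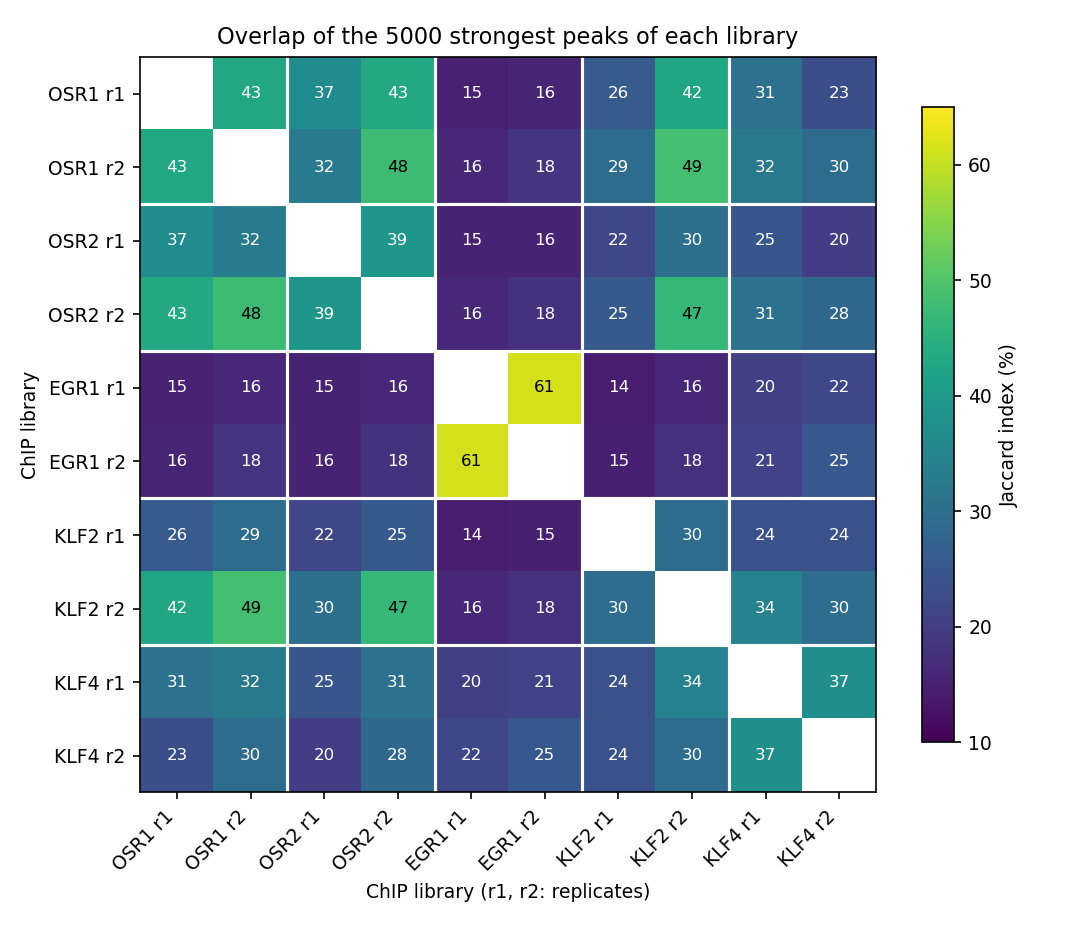
Jaccard index in percent between the 5000 strongest peaks of each pair of the 10 libraries, with libraries on both axes and the colour scale and printed numbers giving the index. The EGR1 replicates form the brightest cell at 61.5%, and OSR1 replicate 2 and KLF2 replicate 2 share 48.7%.

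The next comparison asked whether factors of one family shared more binding. OSR1 and OSR2 had the highest overlap of any pair of factors, with a mean Jaccard index of 40.0% ± 6.75 (SD over 4 library pairs). That rank depends on KLF2 replicate 1: KLF2 replicate 2 alone shared 42.5% and 48.7% with the OSR1 libraries. KLF2 and KLF4 shared 27.9% ± 5.11, less than KLF2 shared with OSR1 (36.6% ± 10.8) or with OSR2 (31.0% ± 10.97). Much of this spread lay between the 2 KLF2 libraries. KLF2 replicate 1 shared 25.8% and 29.5% with the OSR1 libraries, and 23.6% and 24.0% with those of KLF4. For KLF2 replicate 2 the values were 42.5% and 48.7% against 34.4% and 29.6%. With OSR2 the order was mixed, at 21.8% and 25.5% for KLF2 replicate 1 and 30.2% and 46.6% for replicate 2. These differences were not tested. The mean of the same-family pairs was 33.9% and that of the other pairs 24.1%. This was the largest of the 15 possible choices of 2 separate factor pairs (exact test, one-sided p = 0.0667, the smallest p the design allows, so it cannot pass 0.05). With the 20000 strongest peaks it was not the largest (32.3%, exact p = 0.133). EGR1 was the factor farthest from all others. Its mean Jaccard index was 22.1% ± 1.93 (SD, n = 2 libraries) with KLF4, 16.3% ± 1.38 with OSR1, 16.2% ± 1.12 with OSR2 and 15.7% ± 1.70 with KLF2. KLF4 libraries were nearer to EGR1 than any other pair of the 8 libraries (exact test over 28 choices, one-sided p = 0.0357, the smallest they allow, and adjusted p = 0.143 over the 4 factors compared). This test was chosen after the data were seen.

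Peaks found in both replicates at a q-value of 0.01 or less numbered 72953 for OSR1, 69081 for OSR2, 74487 for EGR1, 40520 for KLF4 and 30019 for KLF2. Such reproducible peaks were shared widely between factors. On assembled chromosomes, 69.5% of KLF4 peaks overlapped an EGR1 peak, 68.1% an OSR1 peak and 67.1% an OSR2 peak. OSR2 peaks overlapped OSR1 peaks in 61.5% of cases. The lowest shares were 52.5% for OSR1 and EGR1 and 52.8% for KLF2 and KLF4. Shifting one set along the chromosomes left between 2.89% and 5.29% by chance. Against this, overlap was 10.6 times chance for OSR1 and EGR1 and 18.3 times for KLF2 and KLF4, the lowest and highest of the 10 pairs at this setting (permutation test with 1000 circular shifts, adjusted p = 0.001 for each pair, the smallest they can give). Chance overlap depends on the larger set of a pair, which held 38870 peaks for KLF2 and KLF4 and 67608 to 72477 for the others. The high rank of KLF2 and KLF4 thus goes with a low chance share (2.89%) and not with a high shared one. Of EGR1 peaks, 32.5% overlapped no reproducible peak of another factor, against 25.4% for OSR1, 23.9% for OSR2, 17.7% for KLF2 and 13.8% for KLF4. The order of the pairs changed with the setting. KLF2 and KLF4 overlapped 11.4 times chance without peaks present in all 5 factors (range over the 10 pairs 10.1 to 13.8), 6.24 times without the first replicates (OSR2 and KLF4 7.44 times, OSR1 and EGR1 4.68 times) and 249 times among the 2000 strongest reproducible peaks (OSR1 and OSR2 347 times). The shifts do not account for open or gene-rich chromatin that all factors could share, and the numbers of reproducible peaks depend on the threshold. With an irreproducible discovery rate under 0.05, they were 15100 for OSR1, 13045 for OSR2, 19806 for EGR1, 3870 for KLF2 and 9129 for KLF4.

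A core of strong peaks was present whatever the tagged factor. The 5000 strongest peaks of the 10 libraries merged into 18544 sites, of which 704 were in all 10 lists. Among the sites found in both replicates of a factor, these common sites made up 33.2% for KLF2, 26.6% for KLF4, 25.3% for OSR2, 24.1% for OSR1 and 18.7% for EGR1. They ranked near the top of most lists. Their median place was 365 in OSR1 replicate 2 and 374.5 in KLF2 replicate 2, but 1955 in EGR1 replicate 1 and 1771.5 in EGR1 replicate 2. The 5 strongest sites shared by all factors (galGal4 coordinates) were chromosome 2 from 144404166 to 144404963, chromosome 1 from 151154974 to 151155860, chromosome 4 from 70741069 to 70741746, chromosome 1 from 18784329 to 18784997 and chromosome 1 from 58441349 to 58442311. All were among the 100 strongest peaks of every library, with mean enrichment of 66.7-fold ± 14.5, 65.6-fold ± 14.5, 63.8-fold ± 10.3, 66.2-fold ± 12.5 and 58.6-fold ± 9.26 (SD, n = 10 libraries). No gene annotation of this build was used here, so sites are given by position. The count of common sites fell to 143 with the 1000 strongest peaks of each library, and was 1204 without the first replicates.

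**Figure D2:**
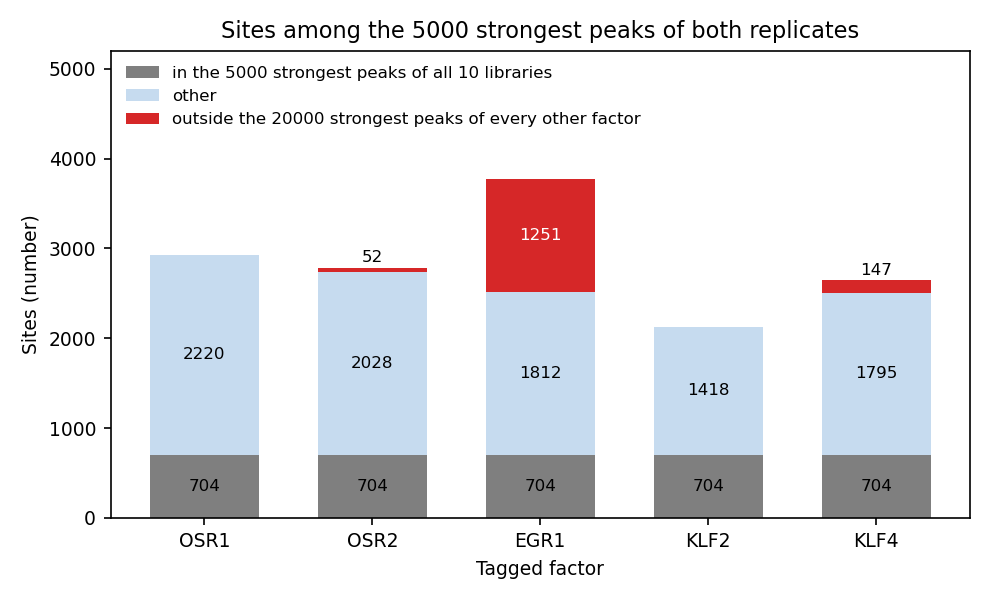
Number of sites found among the 5000 strongest peaks of both replicates of each factor, stacked by sharing: in all 10 libraries (704 sites, grey), other sites (light blue), and outside the 20000 strongest peaks of every other factor (red). EGR1 has 1251 sites in the last class, KLF4 147 and OSR2 52, and OSR1 and KLF2 have none.

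EGR1 had a large set of strong sites that were weak or missing in the lists of the other factors. Of its 3767 sites found in both replicates, 1251 (33.2%, exact 95% confidence interval 31.7% to 34.7%) were outside the 20000 strongest peaks of all 8 other libraries. The 5 strongest EGR1 peaks, none of which met this rule because weaker peaks of other factors were still among their 20000 strongest, were on chromosome 13 from 3517774 to 3518665 (54.4-fold ± 5.00, SD, n = 2), chromosome 23 from 89562 to 90709 (75.0-fold ± 1.04), chromosome 1 from 50104947 to 50106384 (38.6-fold ± 5.04), chromosome 10 from 17279896 to 17280846 (57.8-fold ± 2.20) and chromosome 5 from 36249860 to 36250979 (51.1-fold ± 1.25). At the first of these, 8 libraries of other factors had a peak, none above 4.94-fold. At the second, 6 had a peak and none exceeded 4.62-fold. The highest enrichment of another factor at any of the 5 was 15.8-fold, on chromosome 10. An example from the EGR1-only class is chromosome 11 from 2937224 to 2937836, with 78.2-fold ± 7.62 in EGR1 and at most 3.43-fold in 3 other libraries. The class held 341 sites when any deposited peak of another factor excluded a site, 1973 when the exclusion was limited to their 5000 strongest peaks, and 2235 without the second replicates. With the 1000 strongest peaks it held 221.

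Among the strongest sites, KLF4 shared more of EGR1's than the other factors did. Among reproducible peaks, overlap with EGR1 was 13.1 times chance for KLF4, 12.4 times for KLF2, 10.7 times for OSR2 and 10.6 times for OSR1, an order that changed with the setting, as at a −log10 q of at least 5 (24.0 times for KLF2, 23.4 times for KLF4) and without the first replicates (5.73 times for OSR2, 5.45 times for KLF4). The count of shared peaks was higher for the larger sets of OSR1 (37501) and OSR2 (36413) than for KLF4 (27011) or KLF2 (18310). Of the 3063 EGR1 sites outside the common ones, 35.2% (exact 95% confidence interval 33.5% to 36.9%) were among the 20000 strongest peaks of both KLF4 replicates, against 16.5% for OSR2, 13.5% for KLF2 and 13.2% for OSR1. In the other direction, 75.5% of 1942 KLF4 sites were held by EGR1, 59.2% by OSR2, and 54.6% by OSR1 and by KLF2. EGR1 held 83.7% of 1418 KLF2 sites, 81.8% of 2220 OSR1 sites and 67.2% of 2080 OSR2 sites, so the share of KLF4 sites that EGR1 held was not the highest. These sets differ in how widely the other factors held them. Only for KLF4 sites was EGR1 the factor that held most. OSR2 held 94.5% of the OSR1 sites, OSR1 held 88.5% of the OSR2 sites, and the other factors held 89.1% to 89.7% of the KLF2 sites. The pair EGR1 and KLF4 held 80 sites that were outside the 20000 strongest peaks of the other 3 factors. The strongest of these was on chromosome 18 from 10214077 to 10215079, with 29.3-fold ± 17.9 (SD, n = 4 libraries) in the pair and at most 4.32-fold elsewhere. KLF4 alone held 147 such sites (5.56%), including chromosome 9 from 22843231 to 22843725 (20.9-fold ± 8.59, n = 2) and chromosome 3 from 65620424 to 65621369 (18.6-fold ± 2.79). When any deposited peak of another factor excluded a site, the counts were 0 for the pair and 28 for KLF4, and with the 1000 strongest peaks 5 and 22. They were 274 and 567 without the first replicates, and 275 and 676 without the second.

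OSR1 and OSR2 had a small set of places of their own, which they held together. Sites in both replicates of both factors and outside the 20000 strongest peaks of EGR1, KLF2 and KLF4 numbered 120, while other pairs of factors apart from EGR1 and KLF4 had between 0 and 2. The strongest were on chromosome 12 from 15395871 to 15397031 (23.9-fold ± 8.36, SD, n = 4), chromosome 2 from 67458213 to 67459644 (26.4-fold ± 7.98) and chromosome 3 from 37695120 to 37695768 (21.5-fold ± 2.99). No library of another factor had any peak at chromosome 5 from 37527071 to 37527884 (20.9-fold ± 9.17) or from 10653385 to 10654324 (26.4-fold ± 6.90). OSR2 alone held 52 sites (1.87%), for instance chromosome 8 from 17566616 to 17567324 at 11.6-fold ± 1.89, and OSR1 alone held 0 of 2924. When any deposited peak of another factor excluded a site, the counts were 52 for the OSR pair and 1 for OSR2, and with the 1000 strongest peaks 16 and 0. Without the second replicates they were 314 for the pair, 895 for OSR2 and 129 for OSR1, and without the first 169, 191 and 66. The 5 strongest reproducible peaks of OSR1 and of OSR2 were not of this kind. Together with those of KLF2 they lay at 8 distinct places, all among the 100 strongest peaks in all 10 libraries.

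None of the 2122 sites found in both KLF2 replicates was outside the 20000 strongest peaks of all other factors. The strong KLF2 peaks outside the common sites were held by the other factors as well: of 1418 sites, 89.7% were among the 20000 strongest peaks of both OSR1 replicates, 89.7% among those of OSR2, 89.1% among those of KLF4 and 83.7% among those of EGR1. The 5 strongest KLF2 peaks included chromosome 1 from 18784364 to 18785007 (67.3-fold ± 18.5, SD, n = 2) and chromosome 3 from 107882847 to 107883421 (59.6-fold ± 13.0), both strong in every library. KLF2 and KLF4 held 2 sites as a pair. Without KLF2 replicate 1, the counts were 23 for KLF2, 4 for the pair with KLF4, 1261 for EGR1 and 170 for KLF4. Without the first replicates of all factors KLF2 had 52 such sites and the pair 10, and without the second replicates, where KLF2 replicate 1 stands alone for the factor, 1041 and 32.

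**Figure D3:**
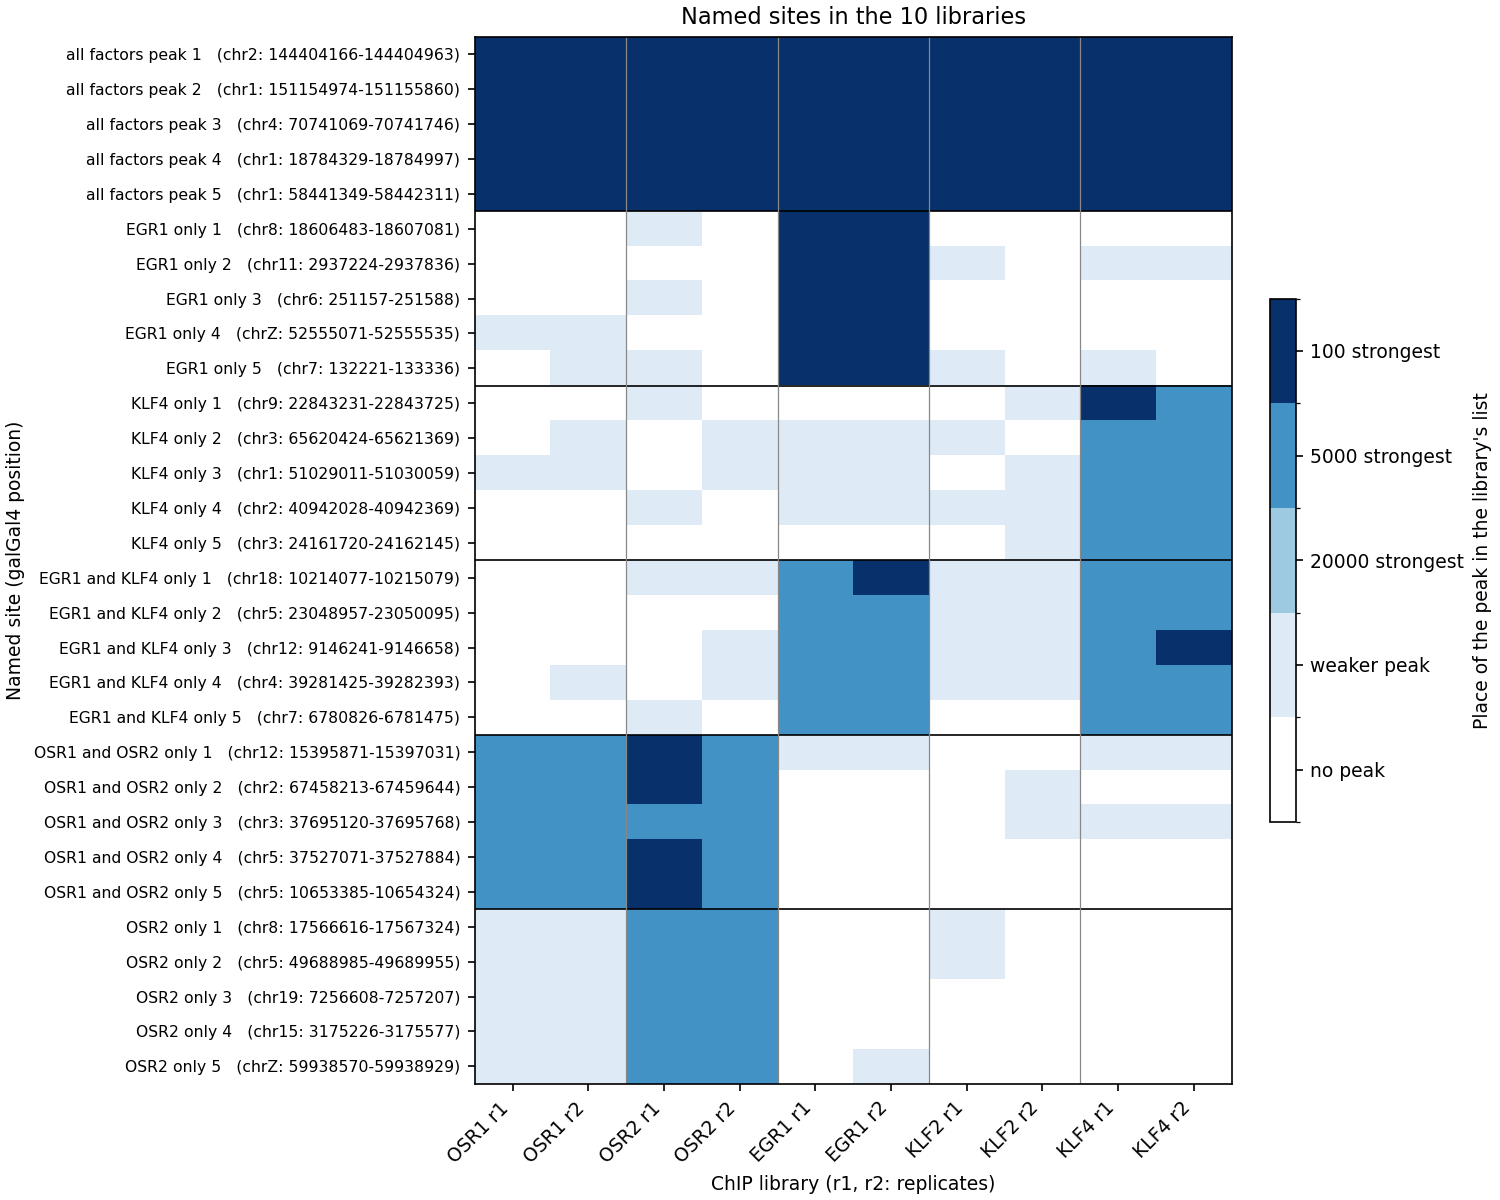
Place of the peak in each library's list, by significance, at the 5 strongest sites of each class (rows, galGal4 positions) in the 10 libraries (columns). Darkest cells are among the 100 strongest peaks and white cells have no peak: the 5 sites shared by all factors are among the 100 strongest in all 10 libraries, and the 5 EGR1-only sites in both EGR1 libraries.

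The last comparison used position along the karyotype, which in birds runs from large macrochromosomes to small, gene-dense microchromosomes. Among the 5000 strongest peaks, those of EGR1 lay least on chromosomes 1 to 5 and most on microchromosomes. This did not extend to all deposited peaks, where EGR1 had 65.0% and 65.6% on chromosomes 1 to 5 and the other libraries 62.3% to 67.3%. The share of the 5000 strongest peaks on chromosomes 1 to 5 was 48.0% ± 0.764 for EGR1, 53.7% ± 2.14 for KLF4, 57.5% ± 6.04 for KLF2, 58.2% ± 2.67 for OSR2 and 61.3% ± 1.81 for OSR1 (SD, n = 2). The share on microchromosomes was 25.1% ± 0.721 for EGR1, 18.8% ± 1.56 for KLF4, 17.2% ± 3.08 for OSR2, 13.4% ± 0.170 for OSR1 and 13.0% ± 0.636 for KLF2. The factors did not differ past the threshold in the first share (exact permutation F test, p = 0.0677), nor with the 1000 strongest peaks (exact p = 0.473) or all peaks with a −log10 q of at least 2 (exact p = 0.863). They did with the 20000 strongest peaks (exact p = 0.0116) and when unplaced sequence was left out (exact p = 0.00529, chosen after the data were seen). They differed in the microchromosome share (exact permutation F test, p = 0.0127, adjusted p = 0.0254 over both shares, chosen after the data were seen). This was not under the threshold with a replicate block (exact permutation F test, p = 0.05) or over all peaks with a −log10 q of at least 2 (exact p = 0.926). The 4 OSR libraries averaged 59.8% ± 2.60 on chromosomes 1 to 5 and the 6 others 53.1% ± 5.13, which did not pass the threshold (exact permutation test, two-sided p = 0.0524).

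**Figure D4:**
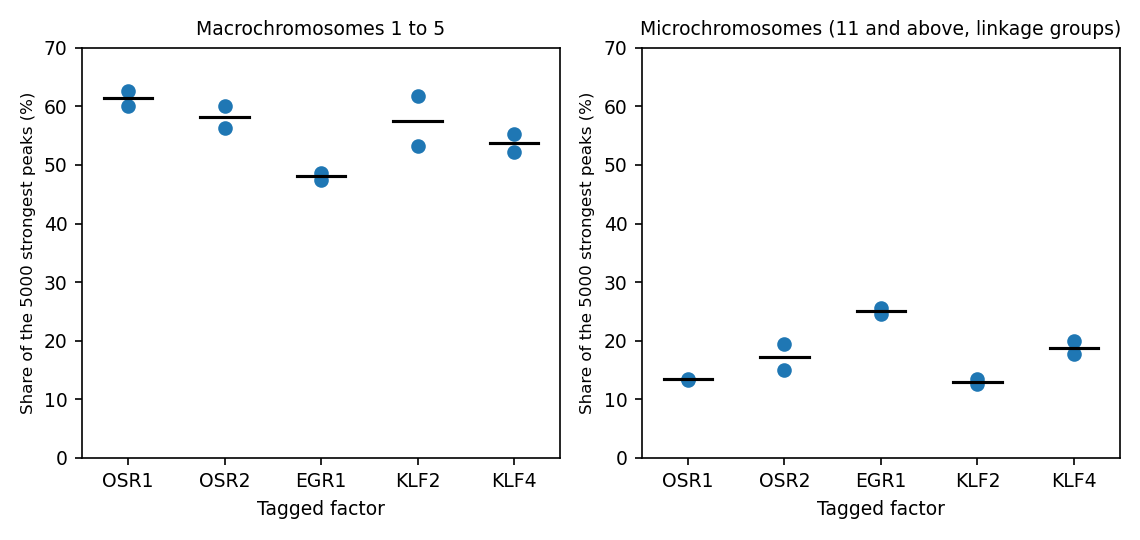
Share in percent of the 5000 strongest peaks on chromosomes 1 to 5 (left) and on microchromosomes (right) for each tagged factor, with a point per library and a line at the mean of the 2 replicates. EGR1 is lowest on the left at 48.0% and highest on the right at 25.1%.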

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

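Library depth is unknown, so lists were compared at equal size, and weak binding in the less enriched libraries, above all KLF2 replicate 1, cannot be told from absence. Alternatives for common, factor-only and pair-only sites, the single-replicate pairwise overlaps, the family overlap without KLF2 replicate 1 and the share on assembled chromosomes alone were chosen after the data were seen. The motif, GC, gene list and own-gene results and the promoter distances were not run, since no galGal4 sequence or annotation was used. The excess of replicate overlap kept its direction and its side of the threshold in all 18 alternatives (24.8% to 46.4%, exact p between 0.00212 and 0.0444), as did pairwise overlap in all 90 (4.68 to 347 times chance). The size of the excess did not hold: over all peaks with a −log10 q of at least 2 it was small, with 24.8% between replicates and 22.8% between factors. Those lists are of unequal length, as with 75852 and 196179 peaks for the KLF2 replicates. Unequal lengths limit the index between replicates and between factors, so this size is not comparable with that at equal set sizes. Family overlap cannot pass the threshold in this design. The family pairs had the highest mean of the 15 choices in 4 of 5 alternatives (exact p = 0.0667, the smallest possible), and not with the 20000 strongest peaks (32.3%, exact p = 0.133). The replicate numbers were not taken as pairs, since deviations of same-numbered libraries did not correlate over 0.1 in each of the 10 factor pairs: they did in the 6 pairs without KLF2 (0.106 to 0.215) and not in the 4 with KLF2 (−0.0191 to 0.0910). Same-numbered libraries of different factors shared 26.9% and differently numbered ones 25.2%, so a shared day is not excluded. With the replicate block the concordance was 42.1% (exact p = 0.00833). Pairwise overlap was there taken from the 5000 strongest peaks of same-numbered libraries, not from reproducible peaks. It was 62.6 to 155 times chance, against 59.6 to 150 for differently numbered libraries. The F value for chromosomes 1 to 5 was 4.52 with the block (exact p = 0.15), with no change of these calls. For the microchromosome share it was 15.9 with the block (exact p = 0.05, no longer under the threshold), against 18.9 without. The block has fewer divisions, but these allow p-values as small as that of the concordance. That share, tested after the data were seen, passed in 3 of 5 alternatives (exact p from 0.0106) and not with all peaks with a −log10 q of at least 2 (F value 0.284, exact p = 0.926), where the cause was not tested. The F value for chromosomes 1 to 5, 4.98 in the main test, passed the threshold at 24.6 with the 20000 strongest peaks (exact p = 0.0116) and at 22.3 on assembled chromosomes (exact p = 0.00529), and fell to 1.08 with the 1000 strongest (exact p = 0.473) and 0.428 with all peaks with a −log10 q of at least 2 (exact p = 0.863). The cause was not tested. Reproducible peaks of OSR1, OSR2, EGR1, KLF2 and KLF4 numbered 36795, 36995, 38748, 9036 and 17636 at a −log10 q of at least 5, and 15100, 13045, 19806, 3870 and 9129 by irreproducible discovery rate, stricter criteria by construction. With all deposited peaks KLF2 had 61649 and KLF4 62625, where the cause was not tested. With overlap of at least 0.5 of both peaks KLF2 had 7440. Peaks of KLF2 replicate 1 had a median width of 67 bp, against 208 bp in replicate 2. A typical peak of the first thus cannot cover 0.5 of a typical peak of the second, so this lower count says little of reproducible binding. A single replicate alone gave 155650 to 194976, 135136 to 160011, 153054 to 202650, 75852 to 196179 and 71801 to 137118. With the 1000 strongest peaks, a smaller set by construction, there were 143 common sites, with 221 EGR1-only, 22 KLF4-only and 0 OSR2-only sites, 16 sites of OSR1 with OSR2, 5 of EGR1 with KLF4 and 0 of KLF2 with KLF4. Ranking by fold enrichment gave 2 KLF2-only sites and 4 of KLF2 with KLF4. When any deposited peak excluded a site, the counts were 341 for EGR1, 28 for KLF4, 1 for OSR2, 52 for OSR1 with OSR2, 1 for KLF2 with KLF4 and 0 for EGR1 with KLF4. When the 5000 strongest did, they were 1973 for EGR1, 407 for KLF4, 304 for OSR2, 87 for OSR1, 73 for KLF2, 193 for EGR1 with KLF4 and 8 for KLF2 with KLF4. Leaving out first replicates, second replicates or KLF2 replicate 1 gave 781 to 1204 common sites, 0 to 129 OSR1-only, 52 to 895 OSR2-only, 1261 to 2235 EGR1-only, 23 to 1041 KLF2-only and 170 to 676 KLF4-only sites. It gave 120 to 314 sites for OSR1 with OSR2, 98 to 275 for EGR1 with KLF4 and 4 to 32 for KLF2 with KLF4. These counts use fewer libraries by construction.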

Other observations

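The comparisons of summits, karyotype and technical explanations below were chosen after the results were seen. Predictions were written before the test itself for the strength order at common sites and the OSR sites in KLF2 replicate 2. The same holds for the strongest peaks of KLF2 replicate 1 over all sequences. The patterns that these tests address had been seen by then. Where EGR1 and KLF4 shared a site outside the strongest peaks of the other factors, their summits often lay apart. At the 80 sites, summits of an EGR1 and a KLF4 library lay a median of 66.5 to 112 bp apart, while those of the EGR1 replicates lay 13.5 bp and those of the KLF4 replicates 35.5 bp apart. Per site, the distance between the factors exceeded that between replicates by 87.4 bp ± 154 (SD) on average and at 62 of the 80 sites (permutation test, two-sided adjusted p = 4.0e-05 over 4 tests, the smallest they can give). Depending on the library pair, 31.2% to 43.8% of the sites had both summits within 50 bp. At the 120 sites of OSR1 and OSR2 no such offset was found: the difference was -0.388 bp ± 13.6, larger between factors at 34 sites (permutation test, two-sided adjusted p = 0.761). At the 704 common sites it was 6.81 bp ± 65.6 for EGR1 and KLF4 (permutation test, adjusted p = 0.00224), larger between factors at 245 sites, with medians of 17.5 bp between factors and 15 bp between replicates, and -0.886 bp ± 30.3 for OSR1 and OSR2 (adjusted p = 0.591). Sites are not independent replicates, so these p-values describe the 4 libraries of each pair. If 2 factors differ in summit precision, the distance between them can exceed the mean replicate distance with no offset. At the common sites the EGR1 replicates lay a median of 10.5 bp and the KLF4 replicates 15 bp apart, so the p-value there does not show an offset. At the 80 sites the p-value has the same limit, but the medians between the factors exceeded those of either factor's replicates.

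The common sites lay less often on microchromosomes than the sites of single factors. Microchromosomes held 19.8% of all sites, 11.1% of the common sites, 33.9% of the EGR1-only sites (Fisher's exact test against common sites, adjusted p = 2.0e-30), 29.9% of the KLF4-only sites (adjusted p = 6.78e-08) and 26.9% of the OSR2-only sites (adjusted p = 0.00298). Sites of a class come from the same few libraries and are not independent, so these p-values describe the sites and not the factors. The OSR2-only share has an exact 95% confidence interval of 15.6% to 41.0%, which holds the share of all sites. The Z chromosome held 10.8% of the common sites and 4.72% of the EGR1-only sites.

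The 704 sites strong in all 10 libraries are not what randomly placed peaks give, since 100 shifts of all lists gave at most 0 sites in all libraries. At most 4 libraries met at a site in any shift. Lists this short leave hardly any other outcome, so the shifts speak against random placement alone. Sequence outside the assembled chromosomes is not the whole cause, with 12.8% of the sites. That share is still above its 7.19% of all sites and its 1.65% of the length that the peaks span, so a part in the pattern is not excluded. Enrichment that does not depend on the tagged factor may account for them. The strength order at these sites correlated on average as well between factors (mean Spearman 0.793) as between replicates (0.797, exact test over divisions of the 10 libraries into pairs, p = 0.401). KLF2 replicate 1 lowered both means, with 0.612 to its own replicate, the lowest of any library pair, and 0.614 to 0.726 to other libraries. Without it, replicates of a factor correlated at 0.815 to 0.864 and libraries of different factors at 0.765 to 0.892. The test was not repeated without this library. Binding of all 5 factors to the same open chromatin would give the same order, and no library without a tagged factor was analysed, so that biological explanation stays open.

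KLF2 replicate 2 shared more with OSR libraries than with KLF2 replicate 1, and the common sites are not the cause, since without them the index was 41.9% with OSR1 replicate 2 and 20.9% with KLF2 replicate 1. It was 35.1% with OSR1 replicate 1, 39.7% with OSR2 replicate 2 and 22.1% with OSR2 replicate 1. The pattern was not particular to OSR libraries: the index was 27.0% with KLF4 replicate 1 and 21.8% with KLF4 replicate 2. An OSR library under a KLF2 name is argued against by sites of the OSR libraries that EGR1, KLF4 and KLF2 replicate 1 lack: KLF2 replicate 2 held at most 2.01% of them, where a left-out OSR1 replicate held 99.3% or 87.7%. Low enrichment in KLF2 replicate 1 could not be decided. Of its 500 strongest peaks outside the common sites, 49.2% were among the 5000 strongest of KLF2 replicate 2 and 71.2% among those of OSR1 replicate 2, but 65% of those peaks lay on unplaced sequence and say little of the factor, and on assembled chromosomes the shares were 68.6% and 69.2%, with overlapping intervals. A library from outside the study under the KLF2 name, and a biological explanation, were not tested.

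For the 1251 EGR1-only sites, no technical explanation was excluded by a test. The counts use sets of fixed size, which the length of a list cannot enter, so that the 744 peaks or fewer in the 5 libraries with longer lists than EGR1 replicate 1 test nothing. The rule also treated the factors unlike, since each factor but EGR1 had to miss the peaks of a family member as well. Sites of a family pair alone, in both replicates of both factors, numbered 120 for OSR1 with OSR2 and 2 for KLF2 with KLF4. Stronger enrichment stays open: KLF2 replicate 2 was as enriched as EGR1 replicate 1 (12.8-fold and 12.4-fold) and had 23 peaks of its own against 1765, but a single library does not decide it, and EGR1 replicate 2 was the most enriched of all at 15.4-fold. A DNA sequence preference of EGR1 unlike that of the other factors is a candidate explanation that was not tested, because no sequence of this genome build was used. Whether the EGR1 libraries differ in another way of preparation stays open as well.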
